A study of Rattus norvegicus with 24 samples.

How the data were processed

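Messenger RNA was sequenced from the liver, brain, thymus and spleen of Sprague-Dawley rats aged 7 months. The 24 libraries fall into 8 groups of 3, one group of SAM-exposed and one of sham-exposed animals per tissue. The series title speaks of PCB exposure (polychlorinated biphenyls, persistent industrial chlorinated compounds) and the treatment label of SAM exposure; the treated group is called SAM here, as in the labels. The labels number the animals 1, 2, 3 and 5 (SAM) and 13 to 17 (Sham), give no dose or duration, and name no sequencing date or batch. Nothing in them says outright that equal numbers in different tissues are the same rat.

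Per the labels' protocols, RNA was purified with RNeasy columns and libraries were made with a stranded TruSeq mRNA kit. Per the submitters' processing notes, STAR 2.2.1 and the rat genome build rn6 were used, with no role given. The counting program, its strand setting and the gene annotation are not given in the sources used here, so reads of overlapping genes and of near-identical copies (Aldh1a7 and Aldh1a1, the Cyp2b, Cyp3a, alpha-globin, immunoglobulin and RT1 families) may be split in a way that cannot be checked, and values of such genes are uncertain. The authors deposited 1 table of whole-number counts per gene, not normalized. Every column name carries the prefix SAM, sham animals included; columns were matched to samples by tissue and animal number, which is unambiguous. The table lists 32883 genes, of which 47 have no gene symbol and 421 symbols stand for more than 1 gene. Library totals ran from 12.9 to 20.1 M (mega) counts. At these depths 1 CPM (counts-per-million) equals 12.9 to 20.1 counts, so values well below 1 CPM rest on few counts. Pairs of replicates differed by 5.95 to 193 times sampling noise (chi-square over its degrees of freedom), so no library was taken for a copy of another.

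Each tissue was analysed alone, SAM minus Sham, with edgeR 4.0.16 in R 4.3.3: genes with too few counts were removed with filterByExpr, libraries were scaled by TMM, and the quasi-likelihood test was adjusted by the Benjamini-Hochberg method at 0.05 over the genes tested. CPM values in the text are TMM-scaled unless raw CPM is stated, and are means ± SD of 3 libraries; log2 fold changes carry their standard error (SE). A gene is said to stand apart where every SAM library lay above, or every one below, each Sham library. Chance gives this for 10% of genes with 3 libraries against 3, if the libraries are exchangeable. Whether the difference varied between tissues was tested with the 3 interaction terms of 1 edgeR fit over all 24 libraries, and with the interaction of thymus and spleen over their 12. Overlaps of calls between pairs of tissues were tested with Fisher's exact test, one-sided.

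Gene lists for programs, cell types, blood and RNA quality, each assigned to the tissues it fits, were written before the data were examined, as were the tests and the rule for naming genes; 642 of their 668 symbols were found. Lists with at least 5 tested members were tested with camera of limma 3.58.1, two-sided, with a preset correlation of 0.01, on voom values, adjusted over the lists of the tissue. The camera test with an estimated correlation, and fry, which asks whether a list's genes move at all, were run beside it. The mixed fry test counts moves in either direction, so it does not show a common one. The directional fry test passed 0 lists in each tissue. The count adjusted over the list alone uses the edgeR p-values of the members only. List scores per library are the mean log2 CPM of the members, with a prior count of 2.

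The naming rule took, per tissue, up to 10 genes from each end of the called genes that stood apart with a mean of at least 1 CPM, or, where fewer than 10 genes qualified, the 10 with the lowest p among genes with a symbol and a mean of at least 1 CPM. It added list members that pass over all genes or over the list alone (at most 4 of a long list) and, whatever their p, the xenobiotic sentinels Cyp1a1, Cyp1a2, Cyp1b1, Ahrr, Tiparp, Nqo1, Cyp2b2 and Cyp3a23/3a1 where tested. Since no gene passed in any tissue, the 10 with the lowest p above that CPM floor are named; statements on the lowest p leave out genes below it. Genes outside the rule were chosen after their values were seen and are said to be so.

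The tests were first tried on simulated counts with known changes. Of the genes changed 2-fold, edgeR recovered 40.3% in liver (11968 genes run), 86.6% in brain (14969), 89.6% in thymus (14882) and 92.5% in spleen (14410). At 1.5-fold the shares were 2.99% in liver, 28.4% in brain, 40.3% in thymus and 62.7% in spleen, and at 4-fold all were recovered. A list planted with a change was called in each tissue and 0 of 20 unchanged lists were. The simulated genes varied independently of one another, whereas members of real lists can be strongly correlated (estimated at 0.992 for mitochondrially encoded genes in thymus). The simulation therefore does not show how often the list test makes false calls in the real libraries. Both interaction tests recovered 200 of 200 genes changed 4-fold, with 8 false calls each. In these simulations only genes well above the count floor were changed and no library stood apart. Each gene had the spread of the fitted trend, or 1 fixed spread in the interaction runs. Recovery in the real libraries may be lower, so a count of 0 calls does not exclude changes of these sizes.

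The alternatives were DESeq2 1.42.0, the RLE scaling, no low-count filter, a filter of 1 CPM in 3 libraries, a single fit of all 24 libraries, limma with sample quality weights, each library left out in turn and, for the interaction tests, the animal number as a block. After the data were seen, 1 surrogate variable (sva 3.50.0) and fits without the libraries that stood apart were added.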

Results

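RNA-seq counts were compared between rats exposed to SAM and sham-exposed rats in 4 tissues, with 3 libraries per group and tissue. Total counts per library, in mega (M), were 13.9 to 18.4 M in liver, 12.9 to 19.6 M in brain, 15.5 to 19.6 M in thymus and 13.3 to 20.1 M in spleen. Some libraries stood apart from the rest of their group. The liver library of SAM animal 1 had 17.8% of its counts on mitochondrially encoded genes, against 5.71 to 8.07% in the other 5 liver libraries. In brain, the libraries of SAM animals 1 and 2 lay at 60.8 and 49.0 on the first principal component, which held 70.3% of the variance, while SAM animal 3 (-24.7) lay inside the sham range of -32.4 to -22.2. In thymus, the mitochondrial share was 5.64% in SAM 1 and 8.18% in Sham 15, against 2.95 to 3.64% in the other 4. Spleen libraries ranged from 3.89 to 5.96%.

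**Figure D1:**
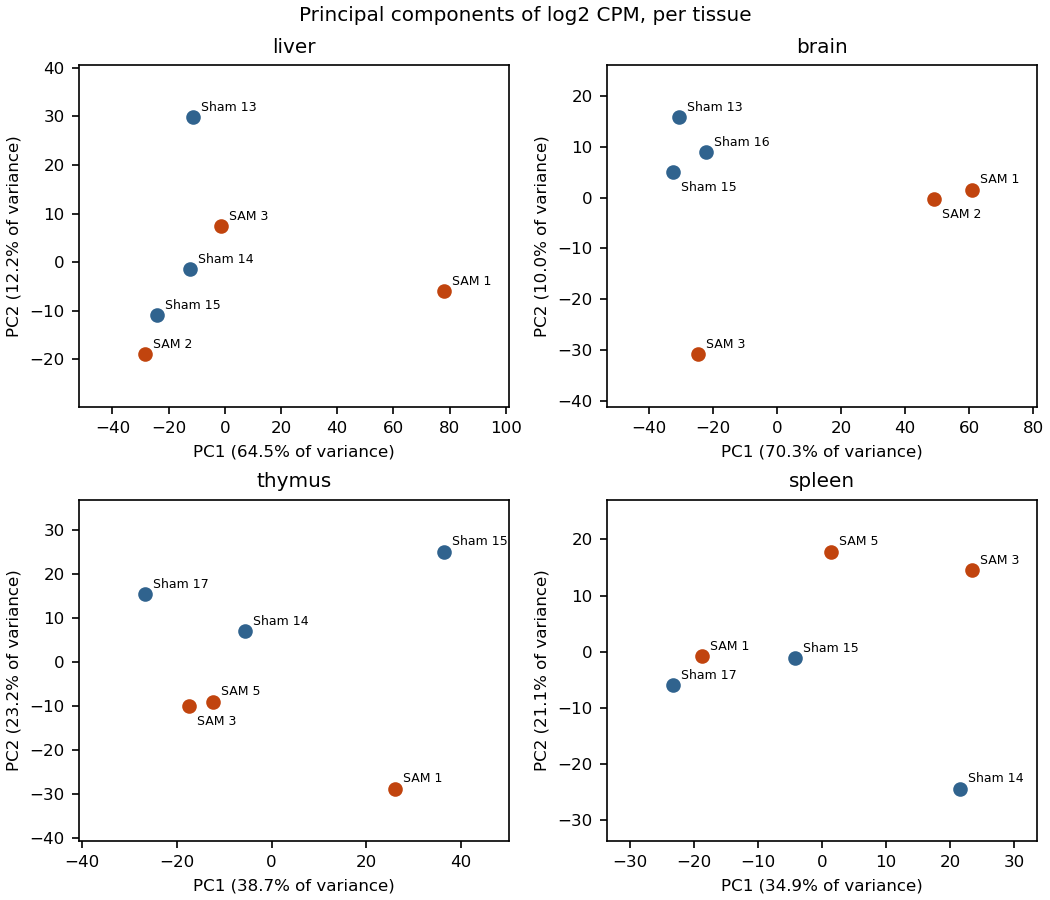
First and second principal components of log2 CPM for the 6 libraries of each tissue, 1 panel per tissue, with each point 1 library labelled by its animal number and coloured by exposure. In brain, SAM 1 and SAM 2 lie at 60.8 and 49.0 on the first component and SAM 3 lies at -24.7, within the sham range.

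The liver comparison asked which transcripts differ between exposed and sham animals in the organ that metabolises most xenobiotics. The gene with the lowest p was Aldh1a7 (ENSRNOG00000017878), an aldehyde dehydrogenase of a phenobarbital-responsive family, at 102 ± 25.0 CPM in SAM and 2.28 ± 1.44 CPM in Sham (SD, n = 3), a log2 fold change of 5.50 ± 0.48 (SE). Cyp1a1 (ENSRNOG00000019500), the classic target of the aryl hydrocarbon receptor (AhR), averaged 15.8 ± 12.9 against 2.39 ± 1.12 CPM, a log2 fold change of 2.71 ± 0.64, or 1.83 ± 0.39 without SAM 1, the library with 17.8% mitochondrial counts, where Cyp1a1 was at 30.3 CPM against 5.65 and 11.4 in the other SAM libraries. With a preset correlation, cholesterol synthesis and fatty acid oxidation genes fell as lists and erythroid and interferon-stimulated genes rose. None of these 4 calls held with an estimated correlation (adjusted p = 0.591 for each). Those of fatty acid oxidation and interferon were also lost without SAM 3 or Sham 15, while the other calls held with each library left out in turn. Other genes of drug metabolism overlapped between the groups: Cyp1a2 averaged 2360.1 ± 941 against 1624 ± 376 CPM, and the log2 fold changes were -0.48 ± 0.27 for Cyp3a23/3a1, 0.36 for Nqo1 and 0.15 for Tiparp. That of Cyp2b2 was 1.46 ± 1.05 and rested on single libraries: it was 3.91 ± 0.77 without Sham 14 (28.0 CPM against 1.14 and 2.78 in the other Sham libraries) and 0.70 ± 0.94 without SAM 1.

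Over the 12130 liver genes tested, edgeR called 0, with 327 at an unadjusted p under 0.05 (217 higher and 110 lower in SAM), and DESeq2 called 2, both higher. Aldh1a7 missed the edgeR threshold with an adjusted p of 0.0518 and passed in DESeq2 at 3.51e-32; without liver SAM 1 it was the 1 gene edgeR called (log2 fold change 5.70, adjusted p 0.000692), and without Sham 13 its log2 fold change was 6.10. Adjusted over the list alone, Aldh1a7 (edgeR adjusted p 9.82e-05) rose among the CAR and PXR targets, receptors that sense drugs and other foreign compounds, and Cyp1a1 (0.0258) rose among the AhR targets. DESeq2 also called Cyp1a1, with an adjusted p of 0.0410. Reads of Aldh1a7 may be shared with its near-identical neighbour in sequence, Aldh1a1, whose own log2 fold change was 0.18 ± 0.21. The next genes by p did not pass in edgeR (adjusted p = 0.802 for Rgs3, the last of them): Ier2 (1.49), an immediate early gene, Dusp6 (1.16), a phosphatase of the ERK kinases, Fabp5 (1.06), a fatty acid carrier, Rgs3 (0.87), Apol3 (0.78), Mettl7a (0.61), Tert (-0.84), the catalytic subunit of telomerase, and Noct (-1.1), nocturnin, a gene with a daily rhythm, on the log2 scale. Groups stood apart for 10.8% of liver genes, against 10% by chance.

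**Figure D2:**
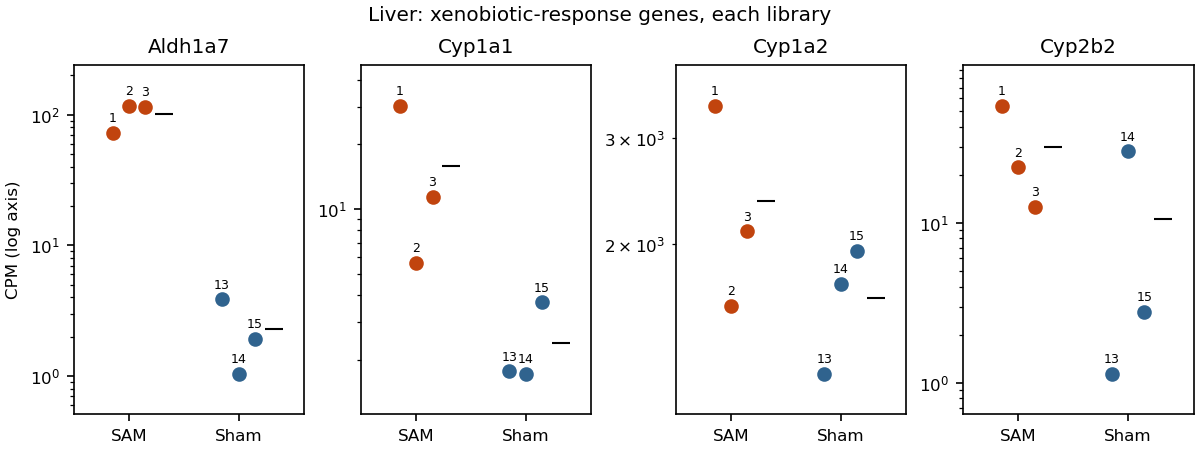
CPM of Aldh1a7, Cyp1a1, Cyp1a2 and Cyp2b2 in each of the 3 SAM and 3 Sham libraries on a log axis; points are libraries and ticks are group means. Aldh1a7 averages 102 CPM in SAM and 2.28 CPM in Sham, and every SAM library lies above every Sham library.

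Of the 22 lists tested in liver, camera called 6 higher and 2 lower; none passed with an estimated correlation. Cholesterol synthesis fell (adjusted p = 0.0003, 17 of 22 members negative and 9 below every sham library), with Idi1 at -0.40, Hmgcs1 at -0.36 and Sqle at -0.34, of which no member passed alone (adjusted p = 0.591 with an estimated correlation). Fatty acid oxidation and PPARA targets fell (adjusted p = 0.0028, 20 of 25 negative), with Vnn1 at -1.15 ± 0.39 and Angptl4 at -0.31; adjusted p = 0.591 with an estimated correlation, and the call was lost without SAM 3 (0.123) or Sham 15 (0.183). Interferon-stimulated genes rose (0.00264, 20 of 29 positive, Oasl 1.13 and Ifi47 0.53), again with adjusted p = 0.591 with an estimated correlation, and without SAM 3 (0.0954) or Sham 15 (0.111) the call was lost. Erythroid and blood genes rose (0.0028, 4 of 5), and adjusted over the list alone 4 rose and 1 fell: both genes named Hba-a2 (1.27 and 1.14), Hbb (0.94) and Alas2 (1.1), for globin and haem synthesis, against Slc4a1 (-0.63), the red cell anion exchanger; adjusted p = 0.591 with an estimated correlation. B cell genes rose (0.0305, 8 of 9, Cd79b 1.02; adjusted p = 0.591 with an estimated correlation), a call lost without SAM 2 (0.386), Sham 13 (0.0744) or Sham 14 (0.259).

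The other 3 liver calls moved with the library of SAM animal 1, the one with 17.8% mitochondrial counts. Ribosomal protein genes rose (adjusted p = 2.27e-08, 75 of 78), as did nuclear-encoded respiratory chain genes (6.34e-07, 67 of 71) and mitochondrially encoded genes (0.00264, 12 of 12), all with adjusted p = 0.684 with an estimated correlation. The ribosomal score was 7.67 log2 CPM in SAM 1 and 6.55 to 6.84 in the other 5 libraries. Without SAM 1 all 3 turned direction, with adjusted p of 0.250, 0.0467 and 0.157; 10 lists were then called in liver, 5 of them called in the same direction in the full set and 1, the respiratory chain list, in the opposite one. The 14 lists that did not pass had adjusted p of 0.0648 (acute phase) or more, among them AhR targets (0.296), CAR and PXR targets (0.347), NRF2 targets (0.347), fatty acid synthesis (0.934), bile acid synthesis and transport (0.187), and thyroid hormone handling (0.0840). By fry, the mixed adjusted p of the CAR and PXR targets was 0.00944, with 12 members positive and 11 negative (median 0.05). Only Aldh1a7 passed over that list alone, and whether the mixed result rests on it was not tested. Cholangiocyte genes had 3 tested members and were not tested as a list, and 0 sex-linked genes passed the filter.

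The brain comparison asked the same of whole-tissue brain RNA. Among genes with a mean of at least 1 CPM, the 10 with the lowest p shared an edgeR adjusted p of 0.221 and did not pass. They were Flna (ENSRNOG00000054890), the actin crosslinker filamin A, at 115 ± 3.04 CPM in SAM and 76.2 ± 3.99 in Sham (log2 fold change 0.59), Nes, the intermediate filament nestin (1.15), Cpxm1 (1.1), Rin3 (0.95), Rarres2 (0.83), RGD1310587 (0.67), Adgra2 (0.58), Ncam2 (-0.63), LOC108348081 (-0.85) and Foxp2 (-1.02). Cyp1b1, an AhR target expressed outside the liver, averaged 7.23 ± 0.806 against 3.13 ± 0.790 CPM, a log2 fold change of 1.20 ± 0.22. With a preset correlation, oligodendrocyte, forebrain excitatory neuron, striatal and cholesterol synthesis genes fell as lists and cytosolic ribosomal protein genes rose. None of these calls held with an estimated correlation (adjusted p = 0.630 to 0.673). The striatal call was also lost without SAM 3, while the others held with each library left out in turn. The median of the excitatory neuron genes was -0.06 with both SAM 1 and SAM 2 left out.

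Over the 15126 brain genes tested, edgeR called 0, with 3108 at an unadjusted p under 0.05 (1806 higher and 1302 lower in SAM), and DESeq2 called 503 (365 higher and 138 lower). Groups stood apart for 23.8% of brain genes, against 10% by chance if all libraries are exchangeable. SAM 1 and SAM 2 lay together far from the other libraries (60.8 and 49.0 on the first principal component). For genes that follow these 2 libraries the 10% is too low, so the excess does not show an effect of exposure. Without brain SAM 3, the exposed library inside the sham range on the first principal component, edgeR called 5896 genes. On the second component SAM 3 lay outside that range, at -30.9 against 4.93 to 15.8 in Sham. It also had the highest mitochondrial share (10.5%) and the lowest total (12.9 M) of the brain libraries. Without both SAM 1 and SAM 2, SAM 3 alone was set against Sham and assumed to vary as the sham libraries do. Sparcl1, chosen after its values were seen, then had a log2 fold change of -5.04.

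Camera called 1 of 23 brain lists higher and 5 lower, and none with an estimated correlation; without SAM 1 it called 10. Cholesterol synthesis fell (adjusted p = 1.35e-06, 21 of 21 members negative, 10 below every sham library), with Stard4 at -0.69 and Hmgcs1 at -0.48; adjusted p = 0.630 with an estimated correlation. Oligodendrocyte genes fell (8.53e-05, 11 of 12; adjusted p = 0.630 with an estimated correlation), and adjusted over the list alone 5 myelin genes fell, Opalin (-0.55), Mal (-0.52), Ermn (-0.48), Mog (-0.48) and Mobp (-0.45). With both SAM 1 and SAM 2 left out, SAM 3 alone was set against the Sham libraries. The cholesterol and oligodendrocyte lists then had medians of -0.19 and -0.51, and Mog was at -0.58. Astrocyte, microglia, endothelium and blood genes had medians of 0.30, 0.46, 0.50 and 1.39, with 0 of 11, 0 of 11, 0 of 10 and 1 of 7 members negative. These values rest on 1 library, so exposure and the composition of that sampled piece cannot be told apart. Heat shock genes fell (0.0213, 10 of 15, Hsph1 -0.41), with an adjusted p of 0.630 with an estimated correlation. That call was lost without SAM 3 (0.0933). By fry, the mixed adjusted p was 0.0202 for both oligodendrocyte and heat shock genes, and the directional one 0.115 and 0.0659. Ribosomal protein genes rose (1.04e-08, 77 of 79; adjusted p = 0.673 with an estimated correlation), with scores of 6.63, 6.52 and 6.41 in SAM and 6.35 to 6.36 in Sham.

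Excitatory neuron genes of the forebrain fell (adjusted p = 0.00016, 12 of 13 negative; adjusted p = 0.673 with an estimated correlation), including Fezf2 (-1.63), Neurod6 (-1.18) and Slc17a7 (-0.58), a vesicular glutamate transporter; the list score was 5.08 in SAM 1, 5.62 in SAM 2, 6.92 in SAM 3 and 6.93 to 7.07 in Sham, and the median was -0.06 with both SAM 1 and SAM 2 left out. Striatal genes fell (0.0141, 10 of 13, Pdyn -1.91 and Drd1 -1.52; adjusted p = 0.673 with an estimated correlation), with scores of 3.68 to 4.0 in SAM and 3.93, 5.23 and 5.37 in Sham; without SAM 3 the call was lost (0.177), and with both SAM 1 and SAM 2 left out all 13 members were negative (median -1.32). Inhibitory neuron genes had a median of 0.78 but a camera direction of down (adjusted p = 0.860): adjusted over the list alone Calb2 (3.93), Dlx2 (2.87), Dlx1 (2.42) and Gad1 (1.97) rose and Lhx6 (-1.53) and Sst (-1.24) fell. With both SAM 1 and SAM 2 left out the rises were gone, with Calb2 at 0.14, Dlx2 at -0.17, Dlx1 at -0.12 and Gad1 at -0.16, and Lhx6 was at -0.76 and Sst at -0.62. Gad1, which makes the transmitter GABA, averaged 994 ± 669 CPM in SAM and 254 ± 11.8 in Sham, with 227 CPM in SAM 3 below all 3 sham libraries (243 to 267).

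**Figure D3:**
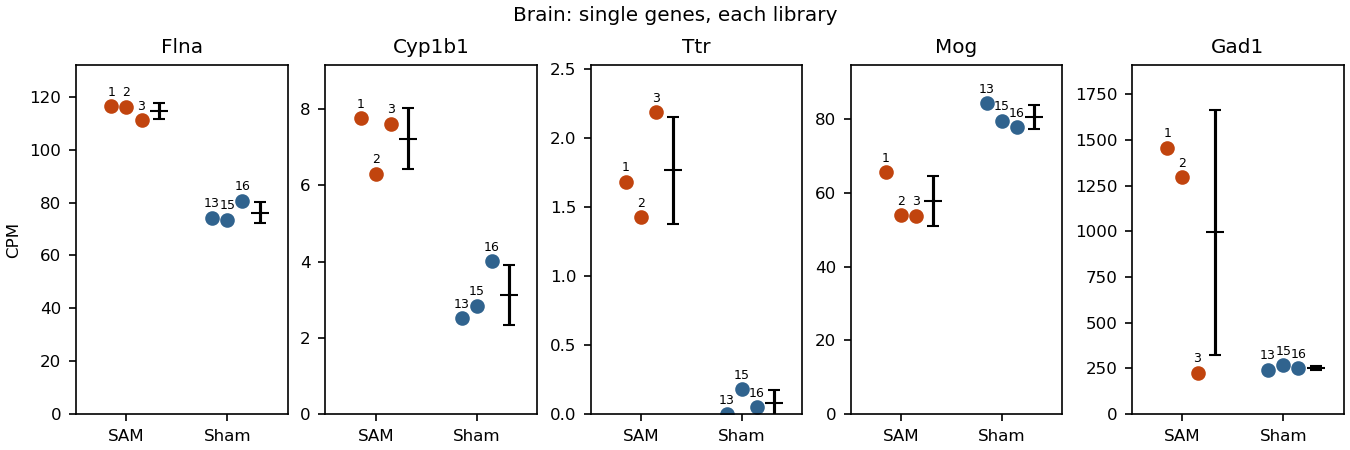
CPM of Flna, Cyp1b1, Ttr, Mog and Gad1 in each brain library, with the mean and SD of the 3 SAM and 3 Sham libraries. Flna averages 115 CPM in SAM and 76.2 in Sham with no overlap, while for Gad1 (994 against 254) SAM 3 lies at 227, just below the sham libraries.

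Further members passed adjusted over their list alone in brain. Cyp1b1 rose among the AhR targets (edgeR adjusted p 0.0072), whose list missed the camera threshold (0.0959) and changed in either direction by fry (mixed adjusted p = 0.00587). Among choroid plexus markers Aqp1 (1.52) rose and Enpp2 (-0.27) fell, and Ttr, the transthyretin carrier of thyroid hormone, was at 1.77 ± 0.387 CPM in SAM and 0.0778 ± 0.0937 in Sham, where no library had more than 3 counts; camera gave 0.212 for that list and fry a mixed adjusted p of 0.00612. Zic1 (1.48) and Zic2 (1.0) of the cerebellum list rose, as did the hormones Trh (5.15) and Crh (1.25) of the hypothalamus and pituitary list. Camera gave adjusted p of 0.860 and 0.0959 for these lists. The cerebellum list had 5 of 9 members negative (median -0.32), so Zic1 and Zic2 alone do not show more cerebellum. The hypothalamic list score was 2.12 in SAM 1, 2.92 in SAM 2 and -0.34 in SAM 3, against -0.90 to 1.45 in Sham. SAM 1 and SAM 2 also held higher olfactory bulb markers, with median log2 ratios over the sham mean of 3.15 and 2.98. With both SAM 1 and SAM 2 left out, SAM 3 was the only SAM library. The log2 fold changes were then 1.39 ± 0.69 for Trh, 0.22 ± 0.35 for Crh, 0.60 for Zic1, 0.66 for Zic2 and 1.05 ± 0.58 for Aqp1. Enpp2 was at -0.17. Cyp1b1 was at 1.28 and Ttr at 4.74, close to their log2 fold changes of 1.20 and 4.42 with all libraries. The log2 fold change of Trh was 4.28 without SAM 1 alone, and that of Aqp1 2.2 without Sham 16. Nqo1 (0.14) and Tiparp (0.23) did not pass. The other lists, including astrocytes (0.991), microglia (0.621), endothelium (0.952), interferon-stimulated genes (0.480) and the circadian clock (0.263), had adjusted p of 0.113 or more, and hepatocyte-abundant genes had 4 tested members and were not tested as a list.

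The thymus comparison addressed the organ of T cell maturation. With a preset correlation, genes of the thymic epithelium, the stroma that selects T cells, fell as a list (adjusted p = 0.607 with an estimated correlation), while no single gene passed in edgeR (lowest adjusted p 0.0877). Krt5 (ENSRNOG00000050420) averaged 328 ± 33.2 CPM in SAM and 606 ± 28.3 in Sham, a log2 fold change of -0.88 ± 0.08, and Krt14, its basal-cell partner, 89.3 ± 8.97 against 152 ± 5.55 (-0.77 ± 0.08). Hyal1, a hyaluronan-degrading enzyme, averaged 4.71 ± 0.188 against 11.7 ± 1.11 CPM (-1.32), and Tecta 178 ± 13.6 against 120 ± 1.31 (0.57). Emp2 (-0.97), Aox2 (-0.96), Fermt1 (-0.90), Cdh3, the basal-layer P-cadherin (-0.83), Olfml2a (-0.81) and Sfrp1, a secreted Wnt antagonist (-0.75), were the other genes with the lowest p.

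None of these passed in edgeR, whose lowest adjusted p was 0.0877, reached by Krt5. Over the 15036 thymus genes tested, edgeR called 0, with 922 at an unadjusted p under 0.05 (249 higher and 673 lower in SAM), and DESeq2 called 100 (8 higher and 92 lower). Groups stood apart for 11.9% of genes, against 10% by chance. With no low-count filter edgeR called 3, Krt5, Krt14 and Hyal1, and no fit without 1 library called any.

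**Figure D4:**
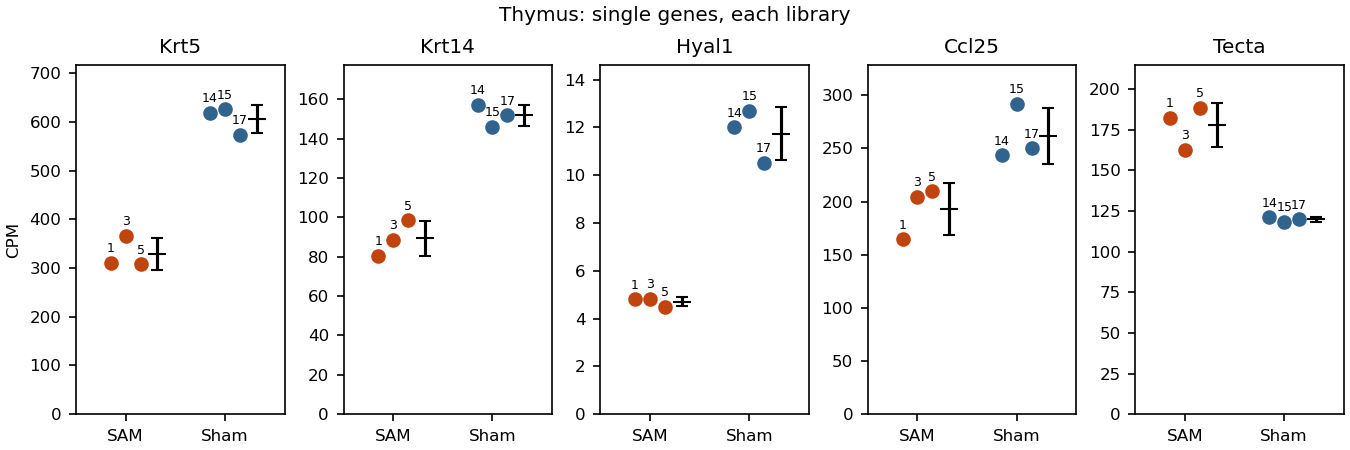
CPM of Krt5, Krt14, Hyal1, Ccl25 and Tecta in each thymus library, with the mean and SD of the 3 SAM and 3 Sham libraries. Krt5 averages 328 CPM in SAM and 606 in Sham, and the groups do not overlap.

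Camera called 3 of 23 thymus lists higher and 3 lower, and none with an estimated correlation. Thymic epithelium genes fell (adjusted p = 5.53e-12, 14 of 14 members negative and 7 below every sham library). With an estimated correlation the camera adjusted p was 0.607. The directional fry test gave an adjusted p of 0.274 and the mixed one 0.0320. Adjusted over the list alone 6 members fell: Krt5, Krt14, Tp63 (-0.58), the basal epithelial regulator, Epcam (-0.58), Krt8 (-0.50) and Ccl25 (-0.44; 193 ± 24.8 against 262 ± 26.3 CPM), a chemokine that draws T cell precursors. The list score was 4.75 in SAM 1, 5.18 and 5.32 in the other SAM libraries, and 5.49 to 5.60 in Sham. SAM 1 and Sham 15 are the libraries of higher mitochondrial share and of higher adipocyte scores (5.82 and 6.15 log2 CPM, against 1.79 to 4.08 in the other 4). With both left out, the median was -0.24 (11 of 14 negative), Krt5 was at -0.82 and Krt14 at -0.72. The other members named above moved closer to 0, with Tp63 at -0.39, Epcam at -0.37, Krt8 at -0.31 and Ccl25 at -0.25. Fibroblast and collagen genes did not pass (0.983; median -0.03).

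Circadian clock genes fell in thymus (adjusted p = 0.000469, 13 of 18; adjusted p = 0.607 with an estimated correlation), with the PAR-domain factor Tef (-0.56) passing over the list alone (edgeR adjusted p 0.0306) and Per3 (-0.47) and Per2 (-0.44) not passing. Proliferation genes rose (8.96e-06, 21 of 21, median 0.13; adjusted p = 0.919 with an estimated correlation). Immature thymocyte genes rose (0.00627, 14 of 16, Ptcra 0.24 and Cd8a 0.12; adjusted p = 0.828 with an estimated correlation), a call lost without SAM 1 (0.209) or Sham 15 (0.159). Ribosomal protein genes rose (9.27e-12, 76 of 81, median 0.07; adjusted p = 0.826 with an estimated correlation). Heat shock genes fell (0.00266, 14 of 15; adjusted p = 0.919 with an estimated correlation), but the list score was 6.66 in Sham 14 and 5.83 to 5.89 in the other 5 libraries, and without Sham 14 the call was lost (0.625). Adjusted over the list alone, Gpx2 (-1.05), a glutathione peroxidase, fell among the NRF2 targets and Sdc1 (-0.91) among the plasma cell genes, neither list passing (0.304 and 0.800). Nqo1 (-0.36), Cyp1b1 (-0.29) and Tiparp (-0.11) did not pass, nor did the AhR target list (0.107). The lists of MHC class II (0.0572), mature T cells (0.0929), B cells (0.0929), adipocytes (0.159), skeletal muscle (0.334) and granulocytes (0.465) did not pass either, though the adipocyte list was called higher without SAM 3 (0.0115), without Sham 15 (3.39e-06) and without both SAM 1 and Sham 15 (3.97e-05). The count of called lists was 7 to 12 with 1 library left out, above 9 without SAM 5 (11), Sham 15 (11) or Sham 17 (12), and 10 without both SAM 1 and Sham 15, of which 5 were shared.

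The spleen comparison covered the peripheral lymphoid organ. P2rx4 (ENSRNOG00000001300), an ATP-gated cation channel, averaged 39.7 ± 3.12 CPM in SAM and 67.3 ± 7.30 in Sham, a log2 fold change of -0.76, and Nlrc5, the activator of MHC class I genes, 116 against 86.8 CPM (0.42). With a preset correlation, interferon-stimulated, T cell, proliferation and erythroid genes rose as lists, and B cell, plasma cell, clock and heat shock genes fell. None of these 8 calls held with an estimated correlation (adjusted p = 0.203 to 0.534). Those of proliferation, erythroid, plasma cell and heat shock genes were also lost without at least 1 library, while the others held with each library left out in turn.

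Over the 14530 spleen genes tested, edgeR called 0, with 597 at an unadjusted p under 0.05 (323 higher and 274 lower in SAM), and DESeq2 called 7 (1 higher and 6 lower), P2rx4 among them at an adjusted p of 6.00e-06. Groups stood apart for 9.22% of genes, against 10% by chance. The lowest edgeR adjusted p was 0.854, for P2rx4. The other genes with the lowest p were Ccdc158 (1.66), Rasa4 (0.49), Nlrc5, Parp14 (0.30), an interferon-inducible ADP-ribosyltransferase, Napsa (-0.32), Mmp12, macrophage elastase (-0.58), Spp1, osteopontin (-1.17), Igkv4-91 (-1.50), an immunoglobulin segment with close copies, and AABR07065815.3 (-2.15). Without SAM 5 edgeR called 1 gene (Hap1), and without Sham 17 also 1 (AABR07065823.1). The sentinels Cyp1b1 (0.09), Nqo1 (-0.25) and Tiparp (-0.02) did not pass.

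Camera called 7 of 21 spleen lists higher and 9 lower; none passed with an estimated correlation, where the adjusted p was 0.203 for the clock list and 0.510 to 0.573 for the other 15. Interferon-stimulated genes rose (adjusted p = 1.40e-08, 28 of 30; adjusted p = 0.510 with an estimated correlation), with Rsad2 at 0.80. Mature T cell genes rose (9.73e-07, 14 of 15; adjusted p = 0.510 with an estimated correlation), and adjusted over the list alone Foxp3, the regulator of regulatory T cells, rose at 13.5 ± 1.32 against 9.01 ± 0.739 CPM (0.59; edgeR adjusted p 0.0262). B cell genes fell (1.21e-05, 11 of 13; adjusted p = 0.510 with an estimated correlation), Pou2af1 (-0.24) and Blk (-0.22) passing over the list alone. Circadian clock genes fell (5.59e-05, 13 of 17; adjusted p = 0.203 with an estimated correlation), with Per2 at -0.41 and Dbp at -0.40. Ribosomal protein genes fell (1.36e-13, 77 of 80, median -0.09; adjusted p = 0.510 with an estimated correlation). These 5 calls held with each library left out in turn.

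The other spleen calls were lost without at least 1 library. Proliferation genes rose (adjusted p = 0.000532, 21 of 21; adjusted p = 0.534 with an estimated correlation), but not without SAM 3 (0.697) or Sham 17 (0.0931). Erythroid genes rose (0.000732, 12 of 12; adjusted p = 0.510 with an estimated correlation), with scores of 6.15, 8.60 and 7.98 in SAM and 7.67, 6.67 and 5.69 in Sham, and lost the call without SAM 3 (0.0578) or Sham 17 (0.0802). Natural killer and cytotoxic genes rose (0.00331, 11 of 12; adjusted p = 0.510 with an estimated correlation), but not without SAM 1 (0.331) or Sham 15 (0.507). Heat shock genes fell (3.77e-05, 15 of 15; adjusted p = 0.510 with an estimated correlation) with a score of 6.73 in Sham 14 and 5.46 to 5.68 in the other 5 libraries, and the call was lost without Sham 14 (0.305). Plasma cell genes fell (0.000774, 10 of 10; adjusted p = 0.510 with an estimated correlation) but not without SAM 5 (0.0880). MHC class II genes fell (0.00246, 10 of 11; adjusted p = 0.510 with an estimated correlation) and lost the call without SAM 1 (0.0681), SAM 3 (0.186), Sham 15 (0.153) or Sham 17 (0.0563).

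Weaker spleen calls were granulocyte genes, which rose (adjusted p = 0.0376, 9 of 13; adjusted p = 0.510 with an estimated correlation), not without SAM 1 (0.186), SAM 5 (0.243), Sham 15 (0.543) or Sham 17 (0.238), and glucocorticoid-responsive genes, which fell (0.0119, 9 of 15, Pdk4 -1.0 and Tsc22d3 -0.56; adjusted p = 0.510 with an estimated correlation), not without SAM 1 (0.149) or Sham 14 (0.613). Immediate early genes fell (0.0421, 9 of 18, Fos -0.78; adjusted p = 0.510 with an estimated correlation), not without SAM 1 (0.109), SAM 3 (0.239) or Sham 14 (0.344). Respiratory chain genes fell (0.00188, 62 of 75; adjusted p = 0.534 with an estimated correlation), not without SAM 3 (0.0503) or Sham 14 (0.664). Mitochondrially encoded genes rose (0.0159, 12 of 12; adjusted p = 0.573 with an estimated correlation), not without SAM 1 (0.559), Sham 14 (0.613) or Sham 15 (0.0806). Red pulp macrophages (0.344), platelets (0.105), fibroblasts (0.223), AhR targets (0.519) and NRF2 targets (0.633) did not pass, and pancreas and hepatocyte genes had 3 and 2 tested members and were not tested as lists. The count of called lists was 10 without SAM 1 and at most 16 with any 1 library left out.

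**Figure D5:**
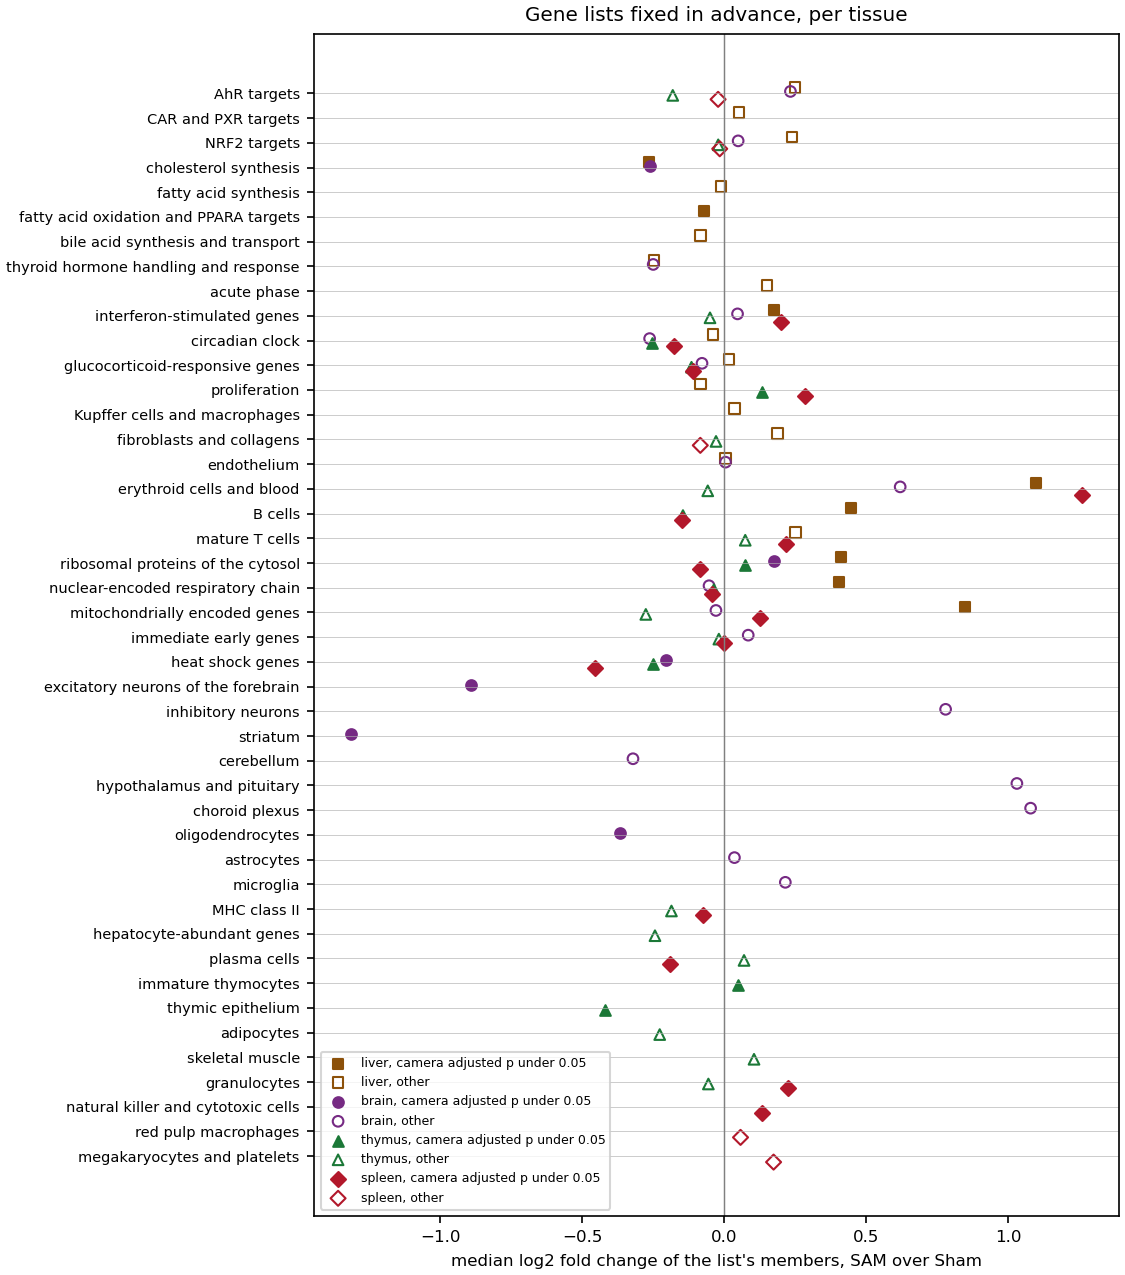
Median log2 fold change (SAM minus Sham) of the members of each gene list per tissue, for lists with at least 5 tested members; shape and colour give the tissue, filled symbols are lists that camera called with its preset correlation and open symbols the others. No list passed with an estimated correlation; the thymic epithelium list has a median of -0.42 and the spleen erythroid list 1.26.

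The interaction test asked whether the difference between SAM and Sham varied among the 4 tissues. Of 17623 genes, edgeR called 2, with 1621 at an unadjusted p under 0.05. Gldc (adjusted p 0.00579), the glycine-cleaving decarboxylase, averaged 0.874 ± 0.308 raw CPM in SAM thymus and 3.52 ± 0.574 in Sham thymus (log2 fold change -1.98 ± 0.30), with 0.39 ± 0.14 in liver and 0.26 ± 0.15 in brain. Scin (0.0217), the actin-severing scinderin, averaged 3.64 ± 2.90 raw CPM in SAM brain and 0.0170 ± 0.0295 in Sham brain, where no library had more than 1 count, with log2 fold changes of 0.03 in thymus and 0.04 in spleen. The next 8 genes did not pass: Plbd1, Eya2, Spp1, Dusp6 and Ebf3 (all 0.0627), Eomes (0.0636), Svil (0.0770) and Cyp39a1 (0.0797). Of these, 7 had their largest difference in brain and Dusp6 had it in liver. The SD in SAM brain was wide for most of them (Spp1 58.3 ± 52.7 raw CPM in SAM and 0.876 ± 0.575 in Sham). It was narrow for Plbd1 (1.12 ± 0.124 in SAM and 0.286 ± 0.161 in Sham). The count depended on single libraries: it was 990 without brain SAM 3, 68 without liver SAM 2, 11 without brain Sham 16, 5 without liver SAM 1, 1 without brain SAM 1, SAM 2 or Sham 15, and 2 or 3 without any other library. Gldc was called in each of the 24 fits with 1 library left out (highest adjusted p 0.0463, without thymus SAM 3), while the call of Scin was lost without brain SAM 1 (0.0648), SAM 2 (0.0781), Sham 13 (0.123) or Sham 15 (0.148). The fit with the animal number as a block called neither gene, though the labels do not say that numbers pair tissues. Scin stood at 6.29 raw CPM in brain SAM 1, 4.08 in SAM 2 and 0.545 in SAM 3.

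Between thymus and spleen, 0 of 15781 genes were called by edgeR, with 649 at an unadjusted p under 0.05, and DESeq2 called 4. The lowest adjusted p was 0.106, for Hyal1, with log2 fold changes of -1.32 in thymus and 0.11 in spleen. C3ar1, the complement C3a receptor, stood at -1.20 and 0.54, Emp2 at -0.97 and -0.13, Etv5 at -1.22 and 0.07, Kcnn3 at 1.24 and -0.45, and AABR07033887.1 at -0.16 and 0.77; Cdh6, Hrct1, Cxcl1 and Misp completed the 10 lowest p. The fit without spleen SAM 5 called 1 gene (Hap1).

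With 0 edgeR calls in each tissue, 0 genes were shared between any pair of tissues, also at an adjusted p under 0.1. Among DESeq2 calls 2 genes were shared. P2rx4 was lower in thymus (-0.69) and spleen (-0.76), with 0.0277 shared genes expected if the tissues are independent. Fisher's exact test gave p = 0.0274, or 0.329 adjusted over the pairs and both directions. Thymus and spleen libraries carry the same animal numbers, and libraries from the same animals would raise the expected number. Serinc2 was lower in brain and thymus (Fisher's exact p = 0.401).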

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

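The tests of mitochondrial share, of the place of SAM 3, of stromal cells and of cortex against medulla were chosen only after the results were seen; the olfactory bulb test and the comparisons with other splits of the libraries were written before.

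Gldc and Scin drew attention because their difference between SAM and Sham varied between tissues in the interaction test (edgeR adjusted p 0.00579 and 0.0217). Gldc averaged 0.874 raw CPM in SAM thymus and 3.52 in Sham thymus, with log2 fold changes above 0 in liver and brain, and Scin 3.64 ± 2.90 (SD) in SAM brain and 0.0170 in Sham brain. Gldc was called with each library left out in turn, but the call of Scin was lost without brain SAM 1 (adjusted p 0.0648), SAM 2 (0.0781), Sham 13 (0.123) or Sham 15 (0.148), and its 6.29 and 4.08 raw CPM in brain SAM 1 and SAM 2, against 0.545 in SAM 3, come from the libraries that lie apart on the first principal component of brain. Neither gene was called with the animal number as a block. Of 40 assignments of the labels within tissues, the real one included, 13 gave at least as many called genes as the real 2, with up to 6 in another, so chance cannot be excluded for this count. The number of assignments was lowered to 40 to limit computing time, after a larger draw that likewise did not exclude chance had been seen.

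The first principal component of brain, with 70.3% of the variance, separated 2 libraries. SAM 1 and SAM 2 stood at 60.8 and 49.0 on the first principal component and SAM 3 at -24.7, within the sham range. The place of SAM 3 is part of how the pattern was found and is that of 1 library, so an effect of exposure stays open. Mitochondrial share (8.71% in SAM 1 and 8.20% in SAM 2, inside the range of the other 4, 8.04 to 10.5%) argues against RNA quality seen that way. Olfactory bulb in the sampled piece is a candidate explanation: the median log2 ratio over the sham mean of 8 bulb markers with values not seen before was 3.15 in SAM 1 and 2.98 in SAM 2 (upper bound of the central 95% of matched random lists 0.358 and 0.318) and 0.05 in SAM 3, with Cdhr1 at 382 and 452 CPM against 5.64 to 18.1 elsewhere. All 8 genes were also found in sham brain, at 0.979 CPM (Th) or more; whether the bulb was dissected differently was not tested, nor whether SAM 1 and SAM 2 differ from SAM 3 in exposure.

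Thymic epithelial genes fell as a list in the exposed thymuses with a preset correlation (adjusted p = 0.607 with an estimated correlation). Fewer stromal cells of every kind would lower fibroblast genes alike, but the difference of the list means (epithelium minus fibroblasts, SAM minus Sham) was -0.47 ± 0.13 (SE; exact permutation p = 0.1, the smallest possible), with fibroblasts at 0.02 ± 0.11. Less medulla against cortex remains open: the cortical genes Psmb11, Prss16 and Ccl25 averaged -0.38 ± 0.26, within 2 SE of 0, with a score of 5.94 in SAM 1, the SAM library of higher mitochondrial share and adipocyte score, 6.74 and 6.67 in the other SAM libraries and 6.73 to 6.90 in Sham. A lower epithelial content and lower expression per epithelial cell cannot be told apart in bulk RNA, and an effect of exposure may be either; that was not tested.

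With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The number of genes called was 0 in liver (highest other split 1), 0 in brain (0), 0 in thymus (0) and 0 in spleen (0), and 0 between thymus and spleen (0). A count of 0 is reached by every split, so for these gene counts the comparison says nothing about chance. The number of called lists was 8 in liver (highest other 11; 5 splits as large), 6 in brain (10; 9), 6 in thymus (18; 10) and 16 in spleen (15; 1). The thymus split with 18 calls set SAM 1, SAM 3 and Sham 15 against the rest, which points to a structure of the samples. SAM 1 and Sham 15 share a higher mitochondrial share and adipocyte score; whether these drive the split was not tested.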

How the results depend on the processing

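The surrogate variable and the fits with libraries left out together were added after the data were seen. Under DESeq2, RLE, no low-count filter and 1 library left out, of the 783 alternative values of the 87 named results, 697 kept direction and side of the threshold, 80 kept direction and passed, and 6 turned, all Tiparp near 0: with 1 library left out its log2 fold change ran from -0.20 to 0.50 in liver, -0.033 to 0.35 in brain, -0.22 to 0.048 in thymus and -0.065 to 0.0088 in spleen. No named result passed over all genes in the main fit, so none could lose a call. Many were named for a low p, and where groups stand apart, leaving out 1 library can hardly turn the direction. The tally therefore says little about how stable these results are. Named results were not tallied under the 1 CPM filter, the fit of all 24 libraries, the quality weights, the surrogate variable or the fits with 2 libraries left out. In the last, without both SAM 1 and SAM 2 of brain, Dlx2 (2.87 to -0.17), Dlx1 (2.42 to -0.12), Gad1 (1.97 to -0.16) and Tiparp (0.23 to -0.095) turned, and without both SAM 1 and Sham 15 of thymus Tiparp did (-0.11 to 0.036). RLE moved the median gene by at most 0.0075.

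Against 0 edgeR calls in each tissue, DESeq2 called 2 genes in liver, 503 in brain, 100 in thymus and 7 in spleen. A fit of all 24 libraries called 3, 579, 3 and 0; the cause was not tested. No low-count filter gave 1 in liver and 3 in thymus, RLE 1 in liver (Aldh1a7), and quality weights 1 in liver and 6488 in brain, where SAM 3 had a weight of 0.177. The surrogate variable gave 1 in liver, 4 in brain and 8 in thymus. With both doubted brain libraries left out 1 gene was called, and with both thymus ones 0. With 1 library left out the count was 0 to 1 in liver, 0 to 5896 in brain (without SAM 3), 0 to 0 in thymus and 0 to 1 in spleen.

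Called lists fell to 0 in all tissues with an estimated correlation (from 8, 6, 6 and 16), numbered 13 and 10 with both doubted libraries left out in brain and thymus, and 6 to 11, 6 to 10, 7 to 12 and 10 to 16 in liver, brain, thymus and spleen with 1 left out. The 4-tissue interaction count of 2 became 330 in DESeq2, 15 with no filter and 1 to 990 with 1 library left out; the thymus and spleen count of 0 became 4 in DESeq2 and 0 to 1. DESeq2 shared 2 genes between tissues. For these the cause was not tested.

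Animal numbers were tried as a pairing block in the interaction tests, although the labels do not say that they pair tissues: deviations of same-numbered thymus and spleen libraries correlated across genes at -0.01 to 0.20, with 3 of 6 pairs above 0.1, against 1 of 12 pairs with different numbers (median -0.037). Over all tissues 9 of 25 same-numbered and 10 of 83 other pairs passed 0.1, a hint from the data that numbers may mark animals, short of the criterion set for pairing, which asked it of every pair. The block gave 3 genes over 4 tissues (Ubd, Gfap and Anxa1, 0 shared with the 2) and 0 between thymus and spleen. Depth limits low genes: Ttr had at most 3 counts in any sham brain library, at 17.1 to 19.6 M counts per library.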

Other observations

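The pairing of libraries by animal number described here was prompted by Sparcl1; of its tests the first was written before its result was seen and the second after, and the clock test was chosen after the clock lists had been seen.

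Sparcl1, which encodes the matrix protein hevin, was low in the library numbered SAM 3 of every tissue. Raw CPM was 0.916 in liver against 13.1 to 20.8 in the other 5 libraries, 74.7 in brain against 1976 to 2625, 0.678 in thymus against 70.5 to 110, and 2.57 in spleen against 48.9 to 68.4. A hypothesis is that equal numbers are the same rat and that SAM 3 carries a heritable difference at this gene. Among other genes with 1 spleen library at least 2 log2 units from the next, the same-numbered thymus library was the most extreme in the same direction for 1 of 3 genes (33.3%, exact 95% interval 0.840 to 90.6%), too few to decide. Beside that test, genes chosen in thymus gave 3 of 5 in spleen, and genes chosen in liver 22 of 52 in brain, 13 of 47 in thymus and 11 of 45 in spleen, against 16.7% by chance. Nearly all of the liver genes (49, 47 and 45) were picked by liver SAM 1, a library that stands apart, so they are not independent and do not decide either. With a gap of 1 log2 unit, chosen after the first test left so few genes, it was for 18 of 30 (60.0%, exact 95% interval 40.6 to 77.3%). The interval lies above the 16.7% of chance (one-sided exact binomial p = 1.09e-07, which takes genes as independent) but reaches below the stated bound of more than 50%. Genes within an animal are not independent, so whether equal numbers mark the same rat stays open. Whether the low Sparcl1 of SAM 3 is heritable was not tested.

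Clock genes fell as a list in both lymphoid organs with a preset correlation (adjusted p = 0.607 in thymus and 0.203 in spleen with an estimated correlation). Collection at another time of day is a candidate explanation. It predicts that the Per and PAR-factor arm and the Arntl arm move apart. The difference of the arms (SAM minus Sham, log2) was -0.43 ± 0.10 (SE) in thymus, -0.38 ± 0.25 in spleen, -0.23 ± 0.16 in brain and -1.01 ± 0.70 in liver; the exact two-sided permutation p was 0.1 in thymus, the smallest that 3 libraries against 3 allow, 0.2 in spleen, 0.4 in brain and 0.2 in liver. The thymus value passes 2 SE and the spleen value lies within 2 SE of 0, so the prediction was not met in both organs. The labels give no collection time, so time of day and exposure could not be told apart here whatever the arms showed.

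Fn1, fibronectin, and Ascc2 stood apart in the same direction in all 4 tissues, the 2 of 11020 genes to do so, where 0.364 would be expected if tissues were independent; same-numbered libraries from the same animals would raise that number. The log2 fold changes of Fn1 were 0.17 in liver, 0.42 in brain, 0.96 in thymus and 0.23 in spleen, and those of Ascc2 0.21, 0.17, 0.15 and 0.06. Both were chosen after their values were seen.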
